A study of Mus musculus with 16 samples.

How the data were processed

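RNA was measured in homogenates of the whole tibialis anterior, a muscle of the front of the lower leg, from 16 C57BL/6J mouse libraries. All carried floxed alleles of Hic1, a gene for a zinc finger transcriptional repressor. The 7 wild type libraries had no Cre transgene. The 9 knockout libraries carried UBC-CreERT2, a tamoxifen-activated Cre recombinase under a ubiquitously active promoter. Per the labels' protocols, mice received 2.5 mg tamoxifen in 100 µL oil on each of 5 days from 8 weeks of age. A washout of 10 days and an experimental period of 1 year followed before the muscles were taken. The title of the deposited table gives 18 months, while its sheet and the protocol give 1 year, and the protocol's period is used here. Stranded libraries were made from polyadenylated RNA. Because the controls lacked Cre, an effect of the transgene or of recombination itself cannot be separated from loss of Hic1.

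The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) in 1 column per library, per the file headers. The submitters' processing notes name bcl2fastq, TopHat2, Bowtie2 and Cufflinks and the mouse genome build mm10 (GRCm38), with no versions. The gene annotation, the settings and whether fragments were assigned by strand are not given in the sources used here. The table lists 24340 genes, and 1 of its lines was emptied before it was used here. Its smallest value is 0.01, at which 6250 genes stand in all 16 libraries, so a gene listed at 0.01 was not measured above that floor or its estimate failed. Words in place of values left 4 genes out: Myh4 (no value in 15 libraries), Amd1 and Amd2 (5 libraries each) and Ldb3 (3 libraries). Myh4, the main fast myosin of this muscle, was therefore not tested. Columns were assigned to libraries by the presence of Cre and the replicate number in their names. Gene positions are those of the table plus 1, since 7328 of 23201 gene starts equalled those of GENCODE M21 after adding 1 and 706 as written.

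The table holds no read counts, so the number of fragments behind a value is not given. Relative depth was estimated from genes with a mean under 0.3 FPKM, as the inverse of the most frequent ratio of a library's values to those of knockout replicate 1, since the worth of 1 fragment falls with depth. A minority of these genes stood within 0.015 on the log2 scale of that ratio, 86 of 1129 in wild type replicate 5 and 240 to 317 in each other library. Away from it and from ratios 2 times higher or lower, the highest count was 39 in wild type replicate 5. Relative depth ranged from 0.567 in wild type replicate 5 to 1.12, and no other library was below 0.75. It averaged 0.896 ± 0.168 (SD, n = 7) in wild type and 0.898 ± 0.118 (SD, n = 9) in knockout libraries (exact permutation test, two-sided, p = 0.977). No counting interval or detection floor was computed for the comparisons. For the values listed at 0.01 in wild type replicate 5 alone, fragment numbers were estimated. The low values (10th percentile, 0.6048 FPKM) of 162 genes within 10% of the length of Higd1b were taken as the worth of 1 fragment or more in that library. FPKM divides by the total of each library, so a shift of all genes at once is not visible in it.

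Values were analysed as log2(FPKM + 0.5) for the 11921 genes with a mean of at least 0.5 FPKM over all libraries. Fold changes are on this scale and understate the change of genes with low values. Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, robust empirical Bayes variances and two-sided tests. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The library names in the labels fall into 2 series, starting with a number (4 wild type, 3 knockout) or with W (3 wild type, 6 knockout). No label calls these a batch, but the series was kept as a covariate and the knockout effect was also fitted within each series. Hic1 was also tested with an exact two-sided permutation test over all 11440 splits of the libraries.

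Gene lists for 39 cell types, pathways and handling signs were fixed in advance, and 36 had the 3 tested members required. The lymphocyte list had 1 tested member, and the mitochondrially encoded and X-inactivation lists had 0. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists. The genes named were Hic1, then the 8 largest rises and 8 largest falls among genes past the threshold. These needed a mean of at least 1 FPKM, a symbol other than a Gm or Rik number, and the same direction in both series. Up to 3 members with the smallest p in the direction of each list past its threshold were added. Other list members past the threshold are named where a count of 5 or fewer is given or where they illustrate a list. They were chosen after their values were seen. The groups, lists, tests, naming rule and most alternatives were chosen before the data were examined.

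Alternatives covered the pseudocount, the filter on low values, 2 rescalings, the series covariate, each series alone and the replicate number as a block. Others were a Y-linked covariate, library weights, a rank test, each library left out in turn, and camera with an estimated correlation or the fry rotation test. A correction for transcript length and GC content, and fits without 4 or 2 libraries, were added after the data were seen. Length and GC content came from GENCODE M21 and covered 11863 of 11921 tested genes. The same model was tested on simulated data, with 200 of the 11921 genes changed in each of 3 simulated comparisons of knockout with wild type. It recovered 75.6% of genes changed by 0.5, 97.0% of those changed by 1 and 100% of those changed by 2 on the log2 scale. It called 35 of 35163 unchanged genes. The noise was drawn as the model assumes, normal with each gene's fitted spread and alike in all libraries. No shallower library and no shared length or GC trend was simulated, so these rates may not hold in the data. A list shifted by 0.5 was recovered, with 0 other lists called. The simulated noise was independent between genes, whereas the estimated correlation of that list, the collagens, was 0.524 in the data. The simulation therefore does not show how often lists are called falsely when their genes vary together. Figures were drawn with matplotlib 3.10.9.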

Results

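Transcript levels in the whole tibialis anterior were compared between 7 wild type and 9 Hic1 knockout libraries about 1 year after tamoxifen. The design asks how long-term loss of Hic1 changes gene expression in adult skeletal muscle. A whole-muscle homogenate holds myofibres together with stromal, vascular, immune and nerve cells, so each value is an average over all of them. The labels do not say outright that each library is a separate mouse, so the p-values measure the spread between these libraries. Summed FPKM was 518745 ± 26023 (SD, n = 7) in wild type and 536911 ± 43759 (SD, n = 9) in knockout libraries (exact permutation test, two-sided, p = 0.348). Pairwise correlations of log2 values lay between 0.954 and 0.991, and 0 pairs of libraries were identical. Wild type replicate 5 was the shallowest library, with a depth of 0.567 relative to knockout replicate 1.

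Hic1 itself fell to 7.72% of its wild type level in the knockout libraries. The gene lies on the minus strand of chromosome 11 at 75164565 to 75170255 (mm10). It averaged 3.58 ± 0.69 FPKM (SD, n = 7) in wild type and 0.276 ± 0.125 FPKM (SD, n = 9) in knockout libraries, a 12.96-fold difference of means. The highest knockout library, at 0.463 FPKM, was below the lowest wild type library, at 2.69 FPKM, so the target matched the group labels in all 16 libraries. The log2 fold change was -2.33 (95% confidence interval -2.55 to -2.10, limma adjusted p = 2.81e-10). In the exact permutation test p was 8.74e-05, the smallest that 11440 splits can give. The nearest tested plus-strand genes on its 2 sides, Smg6 and Rtn4rl1, rose in knockout libraries, and are named here after their values were seen. Smg6, a nonsense-mediated decay endonuclease at 74925872 to 75164448 of chromosome 11, ends 116 bases from the 3' end of Hic1. It went from 5.37 ± 0.61 FPKM (SD, n = 7) to 9.87 ± 0.62 FPKM (SD, n = 9), a log2 fold change of 0.84 (adjusted p = 9.2e-07). Rtn4rl1, a Nogo receptor homologue at 75193993 to 75267762, had a log2 fold change of 0.82 (adjusted p = 6.5e-04) and missed the threshold within each library name series (adjusted p = 0.0527 and 0.121, with 5.71e-06 to 0.121 over all alternative settings). Dph1 and Ovca2, between Hic1 and Rtn4rl1, had values of 0.08 and 0.05 and did not pass. Apart from Hic1, Smg6 and Rtn4rl1, 0 of 30 tested genes within 1 Mb passed in limma (4 at an unadjusted p under 0.05, smallest adjusted p = 0.302). Strand use in the counting is not given, so fragments of Hic1 and Smg6 that run past their ends cannot be told apart. Which exons are floxed is not given in the sources used here, so the remaining signal cannot be divided between undeleted alleles and a shortened transcript.

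**Figure D1:**
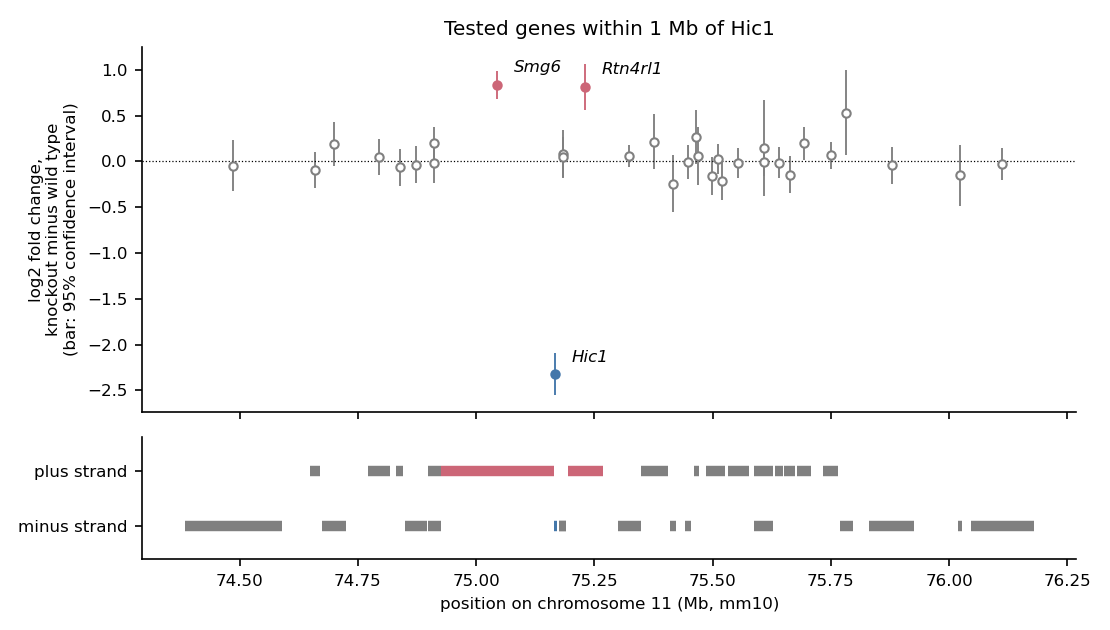
Upper panel, log2 fold change of FPKM + 0.5, knockout minus wild type, with 95% confidence intervals for the 33 tested genes within 1 Mb of Hic1 by position on chromosome 11 (Mb, mm10); lower panel, the extent and strand of each gene, with genes past the adjusted p of 0.05 in colour. Hic1 lies at -2.33, Smg6 at 0.84 and Rtn4rl1 at 0.82, and the other genes lie between -0.25 and 0.53.

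Across the muscle transcriptome a small part differed, with rises and falls in nearly equal number. Of 11921 genes tested, 122 were higher and 120, Hic1 included, were lower in knockout libraries (limma, adjusted p under 0.05), which is 2.03% of the genes. Rises of at least 1 on the log2 scale numbered 30 and falls of that size 14. The 2 groups did not overlap in 93 of the 11921 tested genes, where chance gives 0.0175% or 2.08 genes, and 88 of the 93 were among the 242. All 242 genes, which were called on both series together, had the same direction in the 2 library name series, those starting with a number (number series) and those starting with W (W series).

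**Figure D2:**
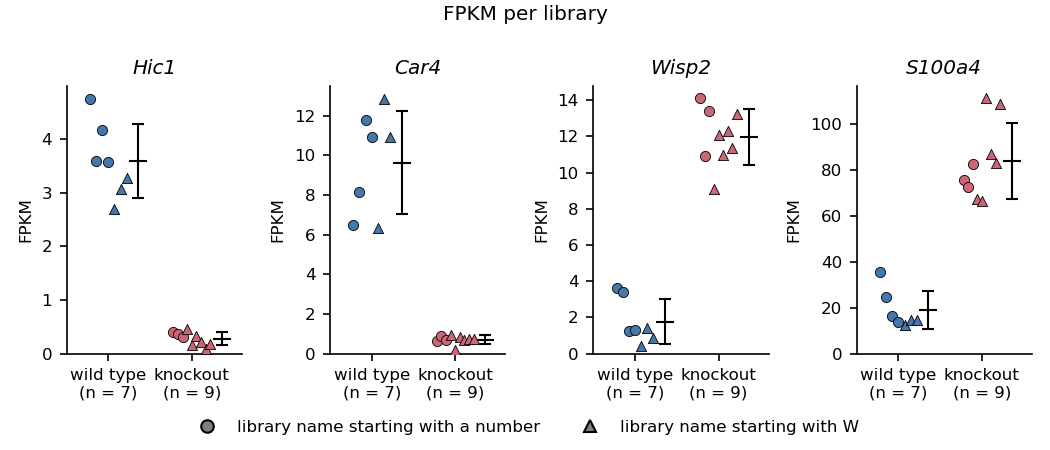
FPKM (linear axes from 0) of Hic1, Car4, Wisp2 and S100a4 in each of 7 wild type (blue) and 9 knockout (red) libraries, with symbols for the 2 library name series and black bars for the mean ± SD. The knockout libraries lie at or below 0.463 FPKM for Hic1 and 0.923 FPKM for Car4, and at or above 9.09 FPKM for Wisp2 and 66.2 FPKM for S100a4, with no overlap between the groups.

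At a pseudocount of 0.5 the largest rise was that of Wisp2, a secreted matricellular protein also called CCN5. It averaged 1.76 ± 1.24 FPKM (SD, n = 7) in wild type and 11.9 ± 1.5 FPKM (SD, n = 9) in knockout libraries, a log2 fold change of 2.76 (SE 0.217, adjusted p = 5.99e-07). Ppp1r1b, which encodes the phosphatase inhibitor DARPP-32, rose by 2.73 (SE 0.155). Aldh3a1, an aldehyde dehydrogenase, rose by 2.30 (SE 0.171). Each was listed at 0.01 in wild type replicate 5 and stayed below 0.8 FPKM in the other 6 wild type libraries (0.141 to 0.784 and 0.109 to 0.786). The order depended on the pseudocount. At 0.1 the log2 fold changes were 3.87 for Ppp1r1b, 3.35 for Aldh3a1 and 3.13 for Wisp2. S100a4, a calcium-binding protein abundant in fibroblasts and some myeloid cells, was the most abundant of these genes. It went from 18.8 ± 8.3 FPKM (SD, n = 7) to 83.7 ± 16.5 FPKM (SD, n = 9), a log2 fold change of 2.24 (adjusted p = 1.52e-06). Rasd1, a Ras-related small GTPase, rose by 1.81, the secreted matrix protein Spon1 by 1.71 and the guidance cue Ntn1 by 1.47. Higd1b, a gene expressed in pericytes, rose by 1.45 (adjusted p = 0.0372), but this size rested on wild type replicate 5, where it was listed at 0.01. The other 6 wild type libraries held 2.54 to 3.44 FPKM and the knockout libraries 3.90 to 8.55 FPKM. Without wild type replicate 5 its log2 fold change was 0.96 (adjusted p = 3.09e-04). It missed the threshold in 13 of 32 alternative settings, with adjusted p-values from 3.09e-04 to 0.281.

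The largest fall was that of Car4, a membrane-anchored carbonic anhydrase of capillary endothelium and muscle membranes. It averaged 9.64 ± 2.62 FPKM (SD, n = 7) in wild type and 0.701 ± 0.216 FPKM (SD, n = 9) in knockout libraries, 13.75-fold lower, with a log2 fold change of -3.06 (SE 0.170, adjusted p = 1.89e-09). Podn, a small leucine-rich proteoglycan of the matrix, went from 6.79 ± 1.13 FPKM (SD, n = 7) to 1.31 ± 0.43 FPKM (SD, n = 9), a log2 fold change of -1.97 (adjusted p = 2.14e-08). Ggt5, a gamma-glutamyltransferase, and Nmb, the peptide neuromedin B, each had a log2 fold change of -1.38. Gpc3, a cell surface heparan sulfate proteoglycan, fell by 1.34 on the log2 scale. Lypd2 fell by 1.27, Adh1, an alcohol and retinol dehydrogenase, by 1.23, and Kcnj8, a potassium channel subunit of pericytes and smooth muscle, by 1.19. Within a single series, Adh1 missed the threshold in the number series (log2 fold change -0.74, adjusted p = 0.271) and Nmb in the W series (log2 fold change -1.08, adjusted p = 0.228). These were the highest values over their alternative settings, the lowest being 5.11e-04 and 6.9e-05. Lypd2 missed it in both.

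**Figure D3:**
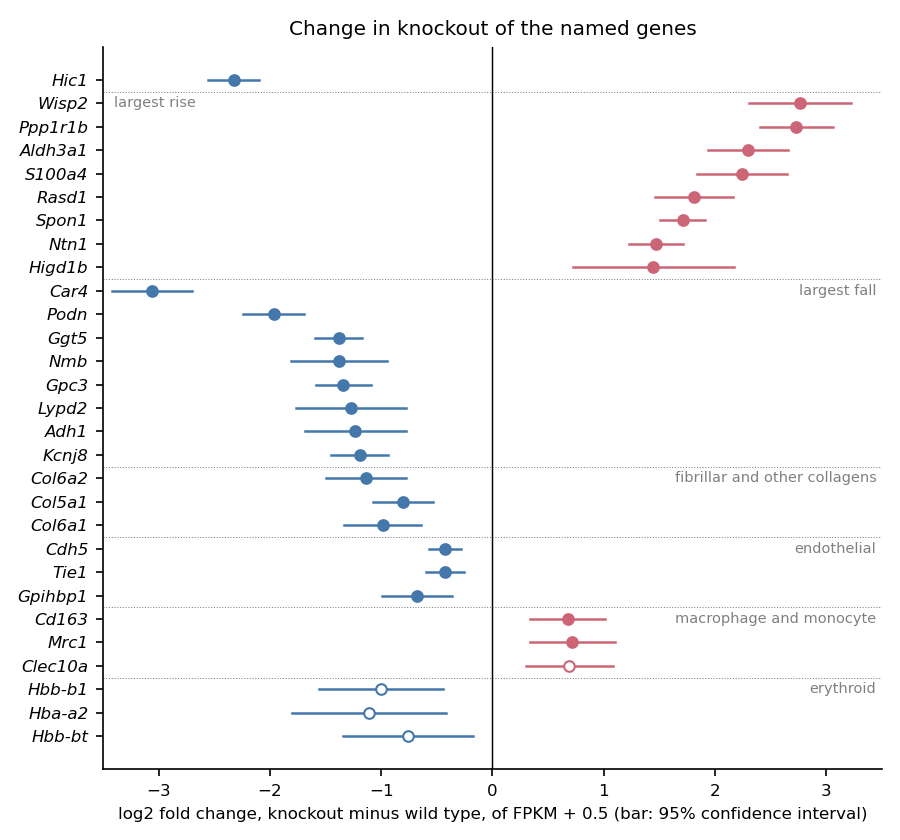
Log2 fold change of FPKM + 0.5, knockout minus wild type (x axis), for Hic1, the 8 largest rises, the 8 largest falls and members of 4 gene lists (y axis); bars are 95% confidence intervals, and filled points passed the adjusted p of 0.05. Wisp2 at 2.76 and Car4 at -3.06 stand at the ends, and the 4 open points (Clec10a, Hbb-b1, Hba-a2 and Hbb-bt) did not pass.

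Of 18 tested fibrillar and other collagen genes 6 fell, 0 rose and 12 did not pass, while 11 fell when adjusted over the list alone. Col6a2, a chain of the collagen VI that surrounds myofibres, went from 24.1 ± 8.1 FPKM (SD, n = 7) to 9.78 ± 1.84 FPKM (SD, n = 9), a log2 fold change of -1.14 (adjusted p = 8.28e-04). Col6a1, its partner chain, fell by 0.99 on the log2 scale and Col5a1, which nucleates collagen fibrils, by 0.81. Col5a3, Col8a1 and Col15a1 also passed, with log2 fold changes of -0.73, -0.56 and -0.63. The main interstitial collagens had values in the same direction that did not pass, -0.63 for Col1a1 (adjusted p = 0.321) and -0.78 for Col3a1 (adjusted p = 0.191). The median over the list was -0.52, and camera gave an adjusted p = 4.44e-13 with the preset correlation and an adjusted p = 0.715 with an estimated correlation. In the W series alone Col6a2, Col6a1 and Col5a1 kept their direction but missed the threshold, with adjusted p-values of 0.117, 0.23 and 0.239, the highest over their alternative settings.

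Other genes of mesenchymal stroma, the connective tissue cells in which Hic1 is expressed, moved both ways. Of 28 mesenchymal progenitor genes 5 were higher, 3 were lower and 20 did not pass (6 and 5 when adjusted over the list alone). The higher ones were Dpp4 (0.73), a marker of adventitial progenitors, the chemokine Cxcl14 (0.62), Thbd (0.54), the small proteoglycan Dcn (0.54) and Efemp1 (0.53). Smoc2 (-0.71), Col15a1 (-0.63) and Tnfaip6 (-0.41) were the lower ones. Dcn was among the most abundant of these, at 350 FPKM in wild type and 481 FPKM in knockout libraries. The matrix protein, crosslinker and protease list held 2 higher genes, Ctgf (0.98) and Fbln5 (0.43), and 2 lower ones, Tnc (-0.72) and Thbs3 (-0.64), of 30 tested (4 and 6 when adjusted over the list alone). In the tendon list Angptl7 rose by 1.37, while Kera and Tnc each had a log2 fold change of -0.72, of 16 tested (3 and 4 when adjusted over the list alone). None of these 3 lists passed camera, with adjusted p-values of 0.695, 0.991 and 0.291. Dcn and Col15a1 missed the threshold in 13 of 32 alternative settings, Fbln5 and Angptl7 in 14 of 32 and Tnc in 20 of 31. Ctgf missed it in 8 of 32, with adjusted p-values up to 0.437, Tnfaip6 in 7 of 31 and Efemp1 in 6 of 32.

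**Figure D4:**
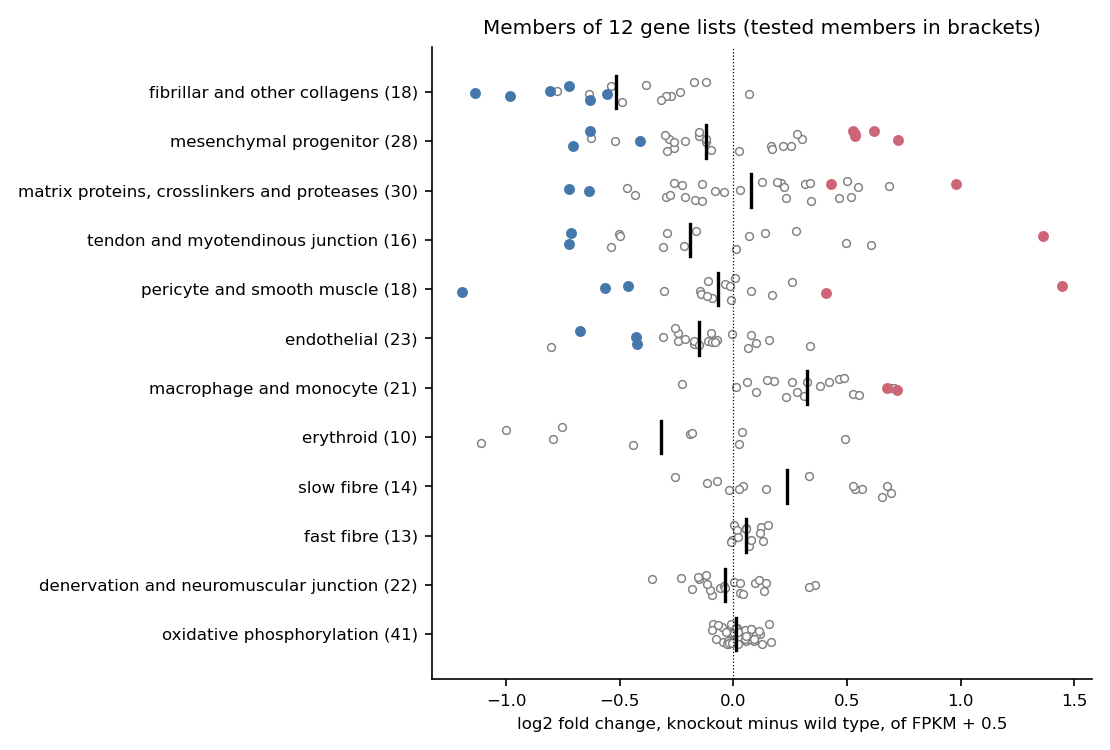
Log2 fold change of FPKM + 0.5, knockout minus wild type (x axis), of each tested member of 12 gene lists (y axis, number of members in brackets), with black bars for the medians; red and blue points rose or fell past the adjusted p of 0.05, and open grey points did not pass. The collagen median lies at -0.52 and the macrophage median at 0.33, while 0 members passed in the fibre type, denervation and oxidative phosphorylation lists.

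Vascular genes changed in part. Of 23 endothelial genes 3 were lower and 0 higher, with 3 lower when adjusted over the list alone. These were the junctional cadherin Cdh5 (-0.43), the receptor Tie1 (-0.43) and Gpihbp1 (-0.68), which anchors lipoprotein lipase in capillaries. Pecam1, another endothelial marker, had a value of 0.16 that did not pass (adjusted p = 0.466). Gpihbp1 missed the threshold without wild type replicate 6 (adjusted p = 0.0677) and without knockout replicate 1 (adjusted p = 0.06), with 0.00354 to 0.434 over all alternative settings. Cdh5 missed it within each series and Tie1 in the W series. Camera placed the list lower with an adjusted p = 0.00194, and with an adjusted p = 0.869 under an estimated correlation. The pericyte and smooth muscle list split, with Kcnj8 (-1.19), the PDGF receptor Pdgfrb (-0.57) and Mcam (-0.47) lower and Higd1b and Notch3 (0.41) higher of 18 tested (4 lower and 2 higher when adjusted over the list alone, camera adjusted p = 0.172). Notch3 missed the threshold in 20 of 32 alternative settings.

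Among 21 macrophage and monocyte genes 2 rose and 0 fell (6 rose when adjusted over the list alone), and 20 had values above 0. Both are scavenger or lectin receptors of tissue-resident macrophages. Cd163 went from 4.46 ± 1.70 FPKM (SD, n = 7) to 6.75 ± 2.21 FPKM (SD, n = 9) and Mrc1 from 3.68 ± 1.51 FPKM (SD, n = 7) to 5.86 ± 1.77 FPKM (SD, n = 9). The log2 fold changes were 0.68 (adjusted p = 0.0305) and 0.72 (adjusted p = 0.0473), close to the threshold, and the rank test passed neither. They missed it in 18 and 25 of 32 alternative settings. Clec10a had a value of 0.69 and did not pass (adjusted p = 0.0682). Camera gave the list an adjusted p = 1.15e-05, and an adjusted p = 0.897 with an estimated correlation. Of 10 erythroid genes 0 passed (4 at an unadjusted p under 0.05, 0 by the rank test and 3 lower when adjusted over the list alone). Camera placed that list lower with an adjusted p = 0.00898 (0.0577 without knockout replicate 3, with 1.38e-13 to 0.884 over all alternative settings), and with an adjusted p = 0.869 under an estimated correlation. Its haemoglobin genes reflect blood in the tissue and share near-identical copies. The values came from the number series, where Hbb-b1 had a log2 fold change of -1.85 and Hba-a2 of -2.08. In the W series these were -0.27 and -0.28, and Hbb-bt was -1.68 in the number series and 0.03 in the W series. Hbb-b1 passed the threshold in 5 of 31 alternative settings, Hba-a2 in 1 of 32 and Hbb-bt in 2 of 32. Their lowest adjusted p-values there were 2.94e-04, 0.0325 and 1.57e-04. All 4 list calls rest on the preset correlation, and as many lists were called in 94 of 100 drawn splits of the libraries, the real split included. Counts of single genes as large as 242 came from the real split alone. In 7 of the 36 lists, 0 of them past the threshold, the median, the mean and the direction of the test differed in sign.

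Single regulators of growth and signalling also changed. Of 12 genes fixed as reported HIC1 targets, 3 passed, and the rest did not (2 higher and 1 lower when adjusted over the list alone). Ccnd1, a G1 cyclin, rose by 0.69 and Cxcl14 by 0.62, while Cdkn1c, a cyclin-dependent kinase inhibitor, had a log2 fold change of -0.46. Among 20 p53 and senescence genes Cdkn1b (0.37) was higher and Cdkn1c lower (3 and 3 when adjusted over the list alone). Of 6 cell cycle genes Ccnd1 was higher and the mitotic kinase Aurka (-0.37) lower (1 and 1 when adjusted over the list alone). The secreted Wnt antagonist Sfrp1 (-0.94) was the single gene of 24 in hedgehog, Wnt and BMP signalling to pass, likewise over the list alone. Cxcl14 and the alarmin Il33 (-0.52) were the chemokine and cytokine genes past the threshold of 18 (2 higher and 2 lower when adjusted over the list alone). C1s1 (-0.48) was the one complement gene of 18 (3 higher and 1 lower when adjusted over the list alone). Notch3, of 14 satellite cell and myogenic genes, Ctgf, of 13 sex hormone responsive genes, and Myc (0.50), of 21 immediate early and stress genes, were the ones past the threshold in those lists and over each list alone. Myc missed it in 26, Aurka in 18 and Cdkn1b in 7 of 32 alternative settings. None of these lists passed camera.

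Myofibre genes of the lists fixed in advance did not pass the test. Whether changed genes outside these lists stem from myofibres was not examined. In the lists of slow fibre, fast fibre, embryonic muscle, denervation and atrophy genes, 0 of 82 members passed in limma or in the rank test, with 5 at an unadjusted p under 0.05. The slow myosin Myh7 had a value of 0.69 with an SE of 0.528 (adjusted p = 0.60). For oxidative phosphorylation, fatty acid oxidation and glycolysis 0 of 90 members passed in either test, with 1 at an unadjusted p under 0.05. Counts were also 0 of 51 for Schwann cell, adipocyte, cartilage and keratinocyte genes, 7 of them at an unadjusted p under 0.05. When adjusted over each list alone, 2 cartilage and bone genes were higher and 1 lower. So were 1 Schwann cell gene, as higher, and 1 keratinocyte gene, as lower. Of 47 antigen presentation, neutrophil and interferon genes 0 passed, 9 at an unadjusted p under 0.05. Over each list alone, 3 neutrophil and mast cell genes were lower, and 1 antigen presentation and 1 interferon gene were higher. Lists that would show handling or time of day (clock, heat shock and ribosome genes) had 0 of 69 passing and 7 at an unadjusted p under 0.05, and 0 of 4 Y-linked genes passed in either test, with 0 at an unadjusted p under 0.05. Across the 20 lists with 0 passing, 33 of 353 members were at an unadjusted p under 0.05 and 0 passed the rank test. In the simulated data 75.6% of single genes changed by 0.5 on the log2 scale were recovered. Those genes were drawn from all tested genes, so this is not the recovery for these lists. It would be lower for a gene as variable as Myh7.

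Between the 2 library name series the knockout effect did not differ past the threshold for any gene. The interaction test gave 0 genes in limma, with 453 at an unadjusted p under 0.05 and a smallest adjusted p of 0.506. Fitted alone, the number series (4 wild type and 3 knockout) gave 46 higher and 49 lower genes. The W series (3 wild type and 6 knockout) gave 38 higher and 16 lower genes.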

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

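The tests of the weighed pattern were chosen after its values were seen. Of 64 groups of libraries examined for a value far from the rest, 4 had one, where chance gives about 1 in 20. In wild type replicate 5, 10676 genes stood at the floor of 0.01 FPKM, against at most 9043 in any other library. In the same library Higd1b was listed at 0.01 FPKM, while the other 6 wild type libraries held 2.54 to 3.44 FPKM. Car4 was lowest in knockout replicate 5, at 0.192 FPKM, where the knockout mean was 0.701 FPKM. Tie1 was lowest in the same library, at 7.45 FPKM, where the knockout mean was 9.97 FPKM.

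The missing Higd1b value was set against 2 technical explanations. This library was the shallowest, at 0.567 of the depth of knockout replicate 1. With the low values of genes of similar length taken as the worth of a fragment, sampling at that depth would leave 0.935 of 9187 genes with a mean of at least 2 FPKM and above 0.5 FPKM elsewhere at the floor in this library alone, against 11 observed, and 3 of these had an estimated 10 or more fragments expected. These numbers rest on that estimate, since the table holds no counts. For Higd1b that estimate used the mean of all other libraries, 4.85 FPKM, against 2.87 FPKM in the other 6 wild type libraries. It also used full transcript lengths. Lower depth alone left fewer such genes on this estimate than were observed, but it is not excluded. A failed estimate for short genes may also be the source. In all, 12 genes within these bounds were listed at 0.01 in this library alone, against at most 1 in any other library. Over the 11 with a known length, their median transcript length was 600 bases against 3303 for genes with a mean of at least 2 FPKM. Short genes hold fewer fragments at the same FPKM, so length does not separate the 2 explanations. Ppp1r1b and Aldh3a1, below 0.5 FPKM in some other libraries, also stood at 0.01 in this library alone. Whether an estimate failed cannot be seen in the table. Without this library the log2 fold change of Higd1b was 0.96, against 1.45 with it.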

How the results depend on the processing

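Hic1 fell in all settings in which it was tested, with log2 fold changes of -2.37 to -2.29 when each library was left out in turn, and was below the filter at a mean of at least 2 FPKM. Leaving out each library gave 88 to 135 higher and 92 to 125 lower genes, and 4 to 6 lists. Against 122 higher and 120 lower genes and 4 lists, a mean of at least 2 FPKM gave 66 and 69, all among the original calls, from 9244 genes tested. The number series alone gave 46 and 49 genes and 8 lists, and the W series alone 38 and 16 genes, from fewer libraries. Library weights gave 211 and 188 genes and 9 lists, and the rank test gave 66 higher genes. Without wild type replicates 1 and 5, a choice made after seeing the data, 9 lists passed. An estimated correlation and the fry test gave 0 lists each, although 11 lists passed fry's test for change in either direction. The cause was not tested except where fewer genes or libraries were used. In the W series the erythroid list turned direction (adjusted p = 0.884), as did Hbb-bt (log2 fold change 0.0316). The correction for length and GC content and the fit without the 4 libraries of highest summed FPKM, both added after seeing the data, kept the gene counts within 1.5 times.

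Replicate numbers showed no clear pairing of the libraries. Of 7 same-numbered pairs, 3 had deviations correlated above 0.1 (range -0.21 to 0.23) and 2 correlated best with their own number. No chance level was computed for these values, so pairing is not excluded. With the replicate number as a block, 71 genes were higher and 74 lower, 69 and 65 of them shared with the original calls. That fit left out knockout replicates 8 and 9, which have no wild type library of their number. Of the 24 genes chosen by the naming rule and past the threshold, besides Hic1, 12 stayed past it in all settings tried, and 0 changed direction. Among 765 gene and setting combinations 74 fell short of the threshold, most often for Mrc1 (25), Cd163 (18) and Higd1b (13). Of 52 other genes named, 336 of 1648 combinations fell short and 0 reversed. The erythroid list also missed the threshold with no filter (adjusted p = 0.0935), with no series covariate (0.101) and after the length and GC correction (0.0661), and the macrophage list in the number series (0.0806). Over all settings the adjusted p-values were 1.38e-13 to 0.884 for the erythroid and 1.53e-11 to 0.897 for the macrophage list. Count models were not run because the table holds no counts. Without counts the precision of low values is unknown, and the shallower wild type replicate 5 limits genes near the floor most.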

Other observations

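The genes in this and the next paragraph were chosen after their values were seen, and each passed the limma test. They were not tested as groups and add nothing to the list tests. Of single genes expressed in myeloid cells some were higher and Ifi30, a lysosomal thiol reductase, was lower (-0.86). The lectin gene Cd209f rose by 1.18 on the log2 scale, Cd209g by 1.00 and Cd209d by 0.77, with the caution that these are close paralogs. F13a1, a coagulation factor made by resident macrophages, rose by 0.90 and the phosphatidylserine receptor Timd4 by 0.65. Cd209d, F13a1 and Timd4 had adjusted p-values of 0.0424, 0.0305 and 0.0287 and missed the threshold in 21, 17 and 15 alternative settings. Cd209g missed it in 12 of 31, with adjusted p-values up to 0.374, whereas Cd209f (adjusted p = 7.84e-04) missed it in 1. Among genes of vitamin A handling, Adh7 rose by 1.14, Aldh1a3 by 0.66 and the retinoic acid binding protein Crabp1 by 1.30, while Adh1 had a log2 fold change of -1.23. Aldh1a3 missed the threshold in 11 of 31 alternative settings, with adjusted p-values up to 0.535. Vim, the intermediate filament of mesenchymal cells, went from 98.6 ± 16.6 FPKM (SD, n = 7) to 159 ± 20 FPKM (SD, n = 9). Penk, the enkephalin precursor, rose by 1.09 and the leptin receptor gene Lepr by 0.87.

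Vessel genes outside the lists also moved both ways. Nos3, the endothelial nitric oxide synthase, had a log2 fold change of -0.52, the arterial connexin Gja5 of -0.54 and the netrin receptor Unc5b of -0.72. Plvap, which forms the diaphragms of fenestrated and venous endothelium, rose by 1.02. Of genes typical of pericytes, Vtn (-0.74) and Enpep (-0.76) were lower and Rgs4 (0.75) and Cox4i2 (0.76) higher. The basement membrane genes Lamc1 (-0.52) and Hspg2 (-0.59) were lower and Lamc3 (1.02), another laminin chain, was higher. Gja5 missed the threshold in 12 of 31 and Cox4i2 in 18 of 32 alternative settings.

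The tests in this paragraph were fixed before their results were seen. Among 100 drawn splits of the 16 libraries into groups of 7 and 9, with the series covariate, 1 gave as many as 242 genes, which was the real split. The highest of the others gave 9 genes, so chance is unlikely as the source of the gene count. With 100 splits, 1 in 100 is the smallest share that can be reached. The other splits also mixed knockout and wild type libraries, which raises the spread within their groups and can lower their counts. For lists, 94 of the 100 splits called at least the 4 of the real split, and the highest of the others called 24, so chance cannot be excluded for the number of lists. Splits that call several times the real count point to a structure of the libraries that moves many genes of a list together.

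The tests of the next 2 patterns were chosen after the values were seen. Camera placed the collagen list lower at the preset correlation (adjusted p = 4.44e-13) and not at an estimated correlation (adjusted p = 0.715). Of its 18 genes 6 fell, while of 28 mesenchymal progenitor genes 5 rose and 3 fell. Counting the real split, 3 of the 100 splits gave the collagen list a camera p as small, and the counts were 14 for the endothelial, 23 for the macrophage and 16 for the erythroid list. As the collagen list had the smallest p of all lists, the smallest p of any list was also compared, and it was as small in 23 of the 100 splits. Variation that a list's genes share between libraries may therefore account for this list call and stays open; the 6 genes each passed their own test. An even fall in the share of all stromal cells is unlikely as the whole source, because it would lower their markers alike and 5 mesenchymal progenitor genes rose. That does not cover a shift between kinds of stromal cells, which was not tested. As part of the source a lower share of stromal cells is not excluded, since 16 of the 28 genes had values below 0 (median -0.12). After the correction for length and GC content, camera at the preset correlation gave the collagen list an adjusted p = 1.95e-08, against 4.44e-13 before it. Over all alternative settings the adjusted p was 5.65e-20 to 0.715, the highest with an estimated correlation. Drawn splits also gave this list small p-values at the preset correlation, so this cannot decide whether length and GC trends were the source. A changed state of the stromal cells that lost Hic1 stays open as well and was not tested.

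Smg6 and Rtn4rl1 rose on either side of Hic1. A shared shift of the genes within 1 Mb is unlikely, because the other 30 tested genes there had a median log2 fold change of -0.00744. That median cannot show changes of single genes in either direction, nor changes farther along the chromosome. Fragments of Hic1 counted for its neighbours would make them fall with Hic1, whereas the 95% intervals of both lay above 0, with 0.563 as the lower of the lower bounds. Transcription that runs on from Hic1 would reach Smg6, 116 bases beyond, on its other strand, and cannot be told apart from Smg6 transcription because the table keeps no strand; it would not reach Rtn4rl1, which lies 23737 bases upstream of Hic1. Relief of local repression by HIC1 or by the deleted segment is a candidate explanation that was not tested.

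Chromosome 11 held 35 of the 242 called genes among its 1016 tested genes (Fisher's exact test, odds ratio 1.84, 95% confidence interval 1.24 to 2.67, adjusted p = 0.0446 over 20 chromosomes). Without 5 Mb on each side of Hic1 it held 29 of 876 (Fisher's exact test, odds ratio 1.77, p = 0.00784, adjusted p = 0.0784 over 20 chromosomes), which missed the threshold. Chromosome 11 also holds Car4, the largest fall, and the rises Ppp1r1b, Aldh3a1, Rasd1, Ntn1 and Higd1b, between 59948214 and 102838039. The other large rises and falls named lie on other chromosomes. What places these changes on the chromosome of Hic1 was not tested, so whether all of them are responses to its loss is not known. Chromosome X held 1 called gene among 368 tested, with 7.47 expected (Fisher's exact test, adjusted p = 0.0761 over 20 chromosomes), which also missed the threshold. The first principal component held 22.8% of the variance, with wild type replicates 5 and 1 lowest at -49.76 and -15.01. Over the 16 libraries it correlated with the slope of each library's values on GC content (Pearson r = -0.909, permutation p = 4e-05, adjusted p = 4e-05; Spearman rho = -0.73, permutation p = 0.00158, adjusted p = 0.00158). Without the 2 libraries farthest from the median slope r was -0.774, and within the number and W series it was -0.934 and -0.942. The second component correlated with the slope on transcript length (r = 0.904, permutation p = 2e-05, adjusted p = 4e-05; rho = 0.829, permutation p = 1.5e-04, adjusted p = 3e-04). There r was 0.82 without the 2 farthest libraries, 0.913 within the W series and 0.0449 within the number series, so it rests on the W series. These were the 2 relations computed. Slopes and components came from the same log2 values, so a trend that varies between libraries can load on a component by construction. The permutation p-values therefore do not compare independent measures. The lowest length slopes were those of knockout replicates 6 to 9 (-0.132, -0.0645, -0.132 and -0.0582). Knockout replicates 1 to 5 lay at 0.017 to 0.0826 and wild type libraries at -0.0369 to 0.0577. The highest GC slopes were those of wild type replicates 5, 1 and 6 (0.203, 0.146 and 0.0923). The other wild type libraries lay at -0.0691 to -0.0333 and the knockout libraries at -0.0901 to 0.00728. The trends were thus uneven between the groups, which was not tested.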
